A study of Mus musculus with 12 samples.

How the data were processed

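Affymetrix 1-colour arrays measured RNA of mouse A2lox.mesp1 embryonic stem (ES) cells, in which doxycycline (dox) switches on a transgene for Mesp1, a transcription factor of early mesoderm. Per the labels' protocols, the cells differentiated in suspension in medium with serum, DKK1, a secreted inhibitor of Wnt signalling, was given at 150 ng/mL from day 0 to day 4, and dox was given at 250 ng/mL from day 2 to day 4. Total RNA was isolated on RNeasy columns and labelled as biotinylated cRNA. The 12 arrays cover 3 days (3, 4 and 6) and 4 arms (untreated, dox, DKK1, DKK1 with dox), with 1 array per condition and no replicate.

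The deposited values were probe set intensity on a linear scale as the authors made it, with a lowest value of 1. How the authors summarised, background corrected and normalized the probes is not given in the sources used here. The column medians of the 12 arrays lay between 28.2 and 31.7 and spanned 0.13 on the log2 scale, under the limit of 0.5 fixed for a further scaling, so the values were used as deposited. Array depth has no count here, and the number of arrays limits the precision.

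Of 45101 probe sets, 34945 named 1 gene, 932 named several genes and 9160 had no gene name in the annotation table used here, and 64 were controls. The 34945 probe sets stood for 18193 genes. Values were transformed as log2 of the intensity plus 8.515, the 20th percentile of all values. Probe sets with at least 2 of 12 arrays above 53.124, the 60th percentile, were kept, and each gene was represented by its probe set with the highest mean, which left 11163 genes. Probe sets for several genes or with no name were left out of the gene comparisons.

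Linear models were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options), with Benjamini-Hochberg adjusted p under 0.05 as the call. The dox and DKK1 effects over 6 pairs used the day and the other treatment as blocks (5 residual degrees of freedom in each fit). The arm and day contrasts came from a fit of day plus arm. The dox effect at day 6 minus that at days 3 and 4 came from a fit of day by DKK1 plus day by dox. A difference between a pair of single arrays is given as a value without a test. The pairs are different conditions and not replicates, and the days may come from a single series of cultures, so the p-values may be too small. The residual spread also holds real differences between days and treatments, so real effects may go uncalled.

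A gene list was described by the mean log2 difference of its measured members, its SD over pairs or arms, an exact two-sided sign-flip test, and limma's camera test with a preset correlation of 0.01 and with an estimated correlation. No camera call held with the estimated correlation. Calls are therefore given with both p-values, except those listed by their means alone among the results flagged for a closer look. The sign-flip test cannot go below 0.0313 over 6 pairs, 0.125 over 4 arms or 0.25 over 3 days. Counts of called members are given over all genes tested and adjusted over the list alone.

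The groups, comparisons, tests, alternatives, 22 gene lists and the rule for named genes were fixed before the data were examined. The lists covered pluripotency, epiblast, primitive streak and nascent mesoderm, Wnt targets, epithelial-mesenchymal transition (EMT) with mesenchymal genes, epithelial genes, cardiac and lateral mesoderm regulators, cardiomyocyte structural genes, smooth muscle, endothelial, haematopoietic, paraxial mesoderm, endoderm, neural and ectoderm, Notch, cell cycle, hypoxia, mitochondrial and amino acid stress, cell death and p53 targets, feeder fibroblast, trophoblast and germ cell genes. Lists of immediate early, Hox, retinoic acid and Wnt inhibitor genes were added after the data were seen, and a heat shock list was written before its values were looked at. Several lists share genes: Foxc2 belongs to 3 of them, and Col1a2 and Col3a1 belong to both the mesenchymal and the fibroblast list. Of 16 trophoblast genes 6 were measured, and 3 of these belong to other lists too, such as Hand1, also a cardiac regulator.

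The named genes were Mesp1 and Mesp2 in each array, the 8 highest and 8 lowest called genes with the same direction in all 6 pairs, the 5 highest and 5 lowest called genes of each other contrast (for day 6 minus day 3, those with the same direction in all 4 arms; for the day 6 dox pairs, those at least 2-fold in both), and up to 4 members with the largest mean change per list. Other genes, given as single array intensities or named behind a small count of called list members, were chosen after their values were seen. Of the 231 genes named by the rule, 103 had more than 1 probe set that passed the filter, and for 2 of these, Tnfrsf19 and Apcdd1, the probe sets differed in the direction of the dox effect.

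The alternatives were other pseudocounts (10th and 40th percentile), quantile normalization, median centring, no filter, a stricter filter, the mean of all probe sets of a gene, other models, limma without trend and robust options, and leaving out each pair, day or arm in turn. Leaving out the day 4 untreated array and a fit on pair differences were added after the data were seen. The calculations were tested on simulated data, in which 92.4% of genes changed 4-fold and 77.6% of genes changed 2-fold were recovered for the dox effect over 6 pairs. Recovery was lowest for the dox effect at day 6 minus days 3 and 4, at 54.5% and 17.9%. False calls made up 6.45% of the calls for dox over 6 pairs. The highest such share was 9.52%, for the difference of the dox effects with and without DKK1. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.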

Results

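The data were 12 arrays of A2lox.mesp1 mouse ES cells differentiating in suspension, 1 for each combination of day 3, 4 or 6 with or without DKK1 and with or without dox. Median intensity lay between 28.2 and 31.7, and 11163 genes passed the filter. The first 3 principal components held 53.1%, 17.4% and 7.8% of the variance. The spike-in control probe sets of the day 4 untreated array lay 0.62 above their mean over arrays on the log2 scale, against −0.25 to 0.16 in the other 11 arrays.

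Mesp1, the gene under the control of dox, was present in untreated cells at an intensity of 285.5 on day 3, 1879 on day 4 and 235.8 on day 6. Dox alone gave 4169, 4415 and 1968 on the same days. With DKK1 alone Mesp1 stood at 67.5, 71.4 and 224.3, and with DKK1 and dox at 4289, 4078 and 1684. Mesp2, its neighbour and relative, ranged from 33.8 to 90.0 over the 12 arrays, with the highest value in the day 4 untreated array. Whether the Mesp1 probe set read the transgene, the endogenous gene or both was not examined.

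**Figure D1:**
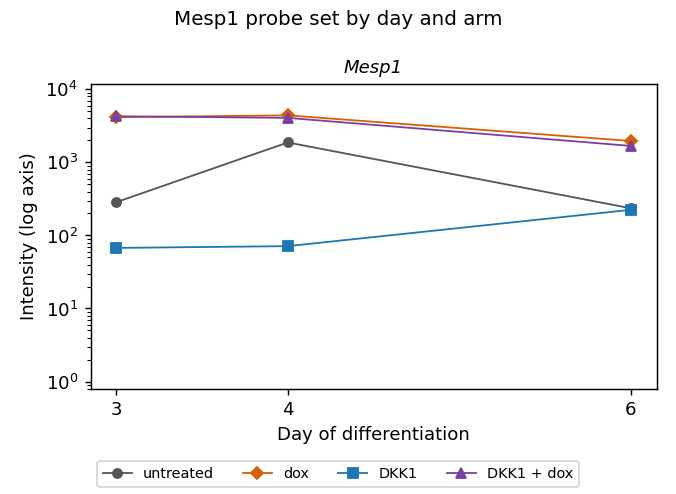
Intensity of the Mesp1 probe set (log axis) against day of differentiation, 1 array per point, with a line for each arm. On days 3 and 4 both arms with dox sat between 4078 and 4415, and DKK1 alone sat at 67.5 and 71.4.

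Over the 6 pairs of arrays with and without dox, which ask what Mesp1 induction does, the highest increases were in Foxc2 (log2 5.95 ± 0.495 SE), a forkhead factor of mesoderm, Myocd (5.02 ± 0.636), a coactivator of muscle genes, Tbx18 (4.95 ± 0.702), and Pdgfra (4.39 ± 0.852), a receptor of mesoderm cells. Tnnt2, the cardiac troponin T gene, rose by 4.19, Meis1 by 3.96, Hand2, a heart regulator, by 3.88 and Aldh1a2, which makes retinoic acid, by 3.77. Foxc2 intensity on day 3 was 3.10 in untreated cells, below the pseudocount of 8.515, and 1270 with dox, and its mean log2 change was 6.31 and 5.28 with pseudocounts at the 10th and 40th percentile. Myocd, Tbx18 and Tnnt2 were also below the pseudocount in arrays without dox, so the size of their changes depended on it (Tbx18 5.42 and 4.15). The largest decreases were in Myb (−3.58 ± 0.628), a factor of blood progenitors, Pim2 (−3.55), Gldc (−3.34 ± 0.343), the glycine cleavage enzyme, and L1td1 (−3.21). Marveld3, a tight junction gene, changed by −3.00, Slc7a3 by −2.93, Pou5f1, the pluripotency factor Oct4, by −2.87 and 1700013H16Rik by −2.87. These 16 genes were chosen among called genes that moved the same way in all 6 pairs. Their adjusted p ran from 0.0035 for Foxc2 to 0.0383 for Pou5f1.

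In total 1773 genes were called for dox, 989 higher and 784 lower (859 and 867 after quantile normalization, 829 and 906 after median centring), of which 487 changed at least 2-fold and 1668 had the same sign in all 6 pairs. Without the day 4 pair with DKK1 279 genes were called, and without single other pairs 741 (day 3 without DKK1), 726 (day 3 with DKK1), 557 (day 4 without DKK1), 1346 (day 6 without DKK1) and 1363 (day 6 with DKK1).

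Of 21 measured EMT and mesenchymal genes 11 rose and 0 fell (18 and 0 adjusted over the list alone), among them Foxc2, Tgfb2 (2.65 ± 0.457) and Zeb1 (2.61 ± 0.45), a repressor of epithelial genes, while Snai2 (2.75, adjusted p = 0.0747) did not pass. The list mean was 1.78 (SD 0.668 over 6 pairs, higher in 6 of 6; camera adjusted p = 5.13e-09, adjusted p = 0.227 with an estimated correlation). Of 26 epithelial genes 15 fell and 0 rose (21 and 1 adjusted over the list alone), including the tight junction genes Cldn6 (−3.20 ± 0.674), Marveld3 and Cldn7 (−2.87 ± 0.601) and the splicing regulator Esrp1 (−2.83 ± 0.65). Their mean was −1.49 (SD 0.943, lower in 6 of 6 pairs; camera adjusted p = 5.66e-08, adjusted p = 0.4 with an estimated correlation). Cdh1, the epithelial cadherin, had an intensity of 1479 on day 4 in untreated cells and 117.2 with dox.

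The list of cardiac and lateral mesoderm regulators, which includes Foxc2 and Pdgfra, had the highest mean. Of 29 cardiac and lateral mesoderm regulators 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a mean of 2.27 (SD 1.21; camera adjusted p = 2.27e-08, adjusted p = 0.319 with an estimated correlation). Of 19 cardiomyocyte structural genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a mean of 1.72 (SD 1.59; camera adjusted p = 3.57e-05, adjusted p = 0.51 with an estimated correlation). The pair means of this list ran from 0.20 on day 3 with DKK1 to 4.50 on day 6 with DKK1. Tnnt2, Bves (2.13), the cardiac actin gene Actc1 (2.12), Cacna1c (1.80) and Tpm1 (0.69) rose, while the myosin light chains Myl7 (2.80, adjusted p = 0.139) and Myl4 (2.75, adjusted p = 0.118) and the troponin gene Tnni1 (2.80, adjusted p = 0.0906) did not pass. Of 12 smooth muscle genes 4 rose and 0 fell (6 and 0 adjusted over the list alone), namely Acta2 (1.70 ± 0.388), Cald1 (0.76 ± 0.0984), Cnn2 (0.68) and Tpm2 (0.60), with a mean of 0.68 (camera adjusted p = 0.00491, adjusted p = 0.502 with an estimated correlation). Of 14 paraxial mesoderm genes Foxc2, Tbx18 and Aldh1a2 rose (3 and 0 adjusted over the list alone), and the list mean was 1.60 (camera adjusted p = 0.0198, adjusted p = 0.597 with an estimated correlation), with −0.45 in the day 6 pair with DKK1.

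Pluripotency and epiblast genes were lower on average. Of 18 pluripotency genes 5 fell and 1 rose (8 and 1 adjusted over the list alone), with Pou5f1, Nanog (−2.76 ± 0.754), Sox2 (−2.24 ± 0.574), Dppa2 (−1.59) and Klf5 (−1.32) lower and Klf4 (1.08) higher, while Utf1 (−2.08, adjusted p = 0.0891) did not pass. Their mean was −0.83 (SD 0.464; camera adjusted p = 0.0185, adjusted p = 0.319 with an estimated correlation). Of 11 epiblast genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with Pim2, Cldn6, Pou3f1 (−3.12 ± 0.717), Otx2 (−2.39 ± 0.622) and the DNA methyltransferase gene Dnmt3b (−1.79) lower and Sox4 (0.49) higher, and a mean of −1.79 (SD 0.725; camera adjusted p = 0.00259, adjusted p = 0.287 with an estimated correlation). Of 7 germ cell genes Sycp3 (−1.56 ± 0.282) and Ifitm3 (−0.86 ± 0.22) fell (0 higher and 2 lower adjusted over the list alone), with a mean of −0.73 (camera adjusted p = 0.016, adjusted p = 0.227 with an estimated correlation). The exact sign-flip test over 6 pairs gave p = 0.0313 (adjusted 0.0688) for each of the EMT, epithelial, cardiac regulator, cardiomyocyte, pluripotency, epiblast and germ cell lists.

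Of 22 mitochondrial and amino acid stress genes 7 fell and 0 rose (14 and 1 adjusted over the list alone), including Trib3 (−2.17 ± 0.446), Mthfd2 (−1.30 ± 0.33) and the amino acid transporter gene Slc7a5 (−1.24 ± 0.227), with a mean of −0.56 (SD 0.238; camera adjusted p = 4.76e-06, adjusted p = 0.227 with an estimated correlation). Of 22 hypoxia genes 4 fell, namely Ddit4 (−0.999 ± 0.092), the glucose transporter gene Slc2a3 (−1.04 ± 0.229), Pdk1 (−1.06 ± 0.281) and the hexokinase gene Hk2 (−0.67). The hypoxia count was also 0 higher and 4 lower adjusted over the list alone, with a mean of −0.34 (camera adjusted p = 0.00433, adjusted p = 0.597 with an estimated correlation), or −0.18 without the day 6 pair without DKK1. Of 15 cell death and p53 targets Pmaip1 (−2.53 ± 0.395), Aen (−0.82 ± 0.204) and Bbc3 (−0.65 ± 0.116) fell, and the list with a mean of −0.28 was not called. Of 27 cell cycle genes 1, Mcm5 (−0.39), fell and 0 rose (0 and 0 adjusted over the list alone), with a mean of −0.35 (SD 0.448; camera adjusted p = 4.13e-05, adjusted p = 0.597 with an estimated correlation). The day 6 pairs carried this mean, at −0.74 without and −1.07 with DKK1, against −0.18 to −0.01 on days 3 and 4.

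Feeder fibroblast genes, markers of cells on which ES cells are often kept, were higher with dox. Of 16 measured genes 6 rose and 0 fell (12 and 0 adjusted over the list alone), including the collagen genes Col1a2 (2.25 ± 0.31) and Col5a2 (2.11 ± 0.537), while Col3a1 (2.40, adjusted p = 0.104) and Lum (2.18, adjusted p = 0.0569) did not pass. The mean was 1.39 (SD 0.678; camera adjusted p = 4.13e-05, adjusted p = 0.227 with an estimated correlation). It was above 0 in 6 of 6 pairs, as was the mean of the EMT and mesenchymal list.

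The other lists were not called for dox over the 6 pairs. Of the primitive streak genes 1 of 20 rose, Pdgfra, with a mean of 0.05 (SD 1.99), a median of −0.33 and a downward camera direction, over pairs that went both ways. On day 4 the primitive streak mean was −2.83 without DKK1, with 15 of 20 genes more than 2-fold lower, and 1.91 with DKK1, and on day 3 it was 0.22 and 2.60. The mean was −0.12 for Wnt targets, over pairs from 1.75 (day 3 with DKK1) to −1.90 (day 6 with DKK1). For Notch genes the mean was 0.39 (median −0.03), over pairs from 1.48 (day 3 with DKK1) to −0.76 (day 6 with DKK1). The list mean was 0.53 for endothelial genes with 0 of 26 called (0.08 without the day 6 pair with DKK1), and −0.41 for haematopoietic genes, of which Myb fell (−0.12 without the day 6 pair without DKK1). Endoderm genes had a mean of 0.58, with Pdgfra, Lama1 (2.55 ± 0.666) and Dab2 (1.60 ± 0.308) higher and Tmprss2 (−1.47) lower. Neural and ectoderm genes had a mean of −0.03 (SD 1.19), with Lhx2 (2.91 ± 0.526) and Ncam1 (1.64) higher and Sox2 and Zic5 (−1.92) lower. Their pairs ran from 0.89 on day 3 without DKK1 to −2.31 on day 6 with DKK1, where 15 of 21 genes were more than 2-fold lower, and the mean without that pair was 0.43. Of 6 trophoblast genes Hand1 (3.18 ± 0.871) and Peg10 (1.16 ± 0.185) rose, with a mean of 1.0. Their pairs went both ways, from 3.10 on day 4 with DKK1 to −1.07 on day 6 without DKK1.

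**Figure D2:**
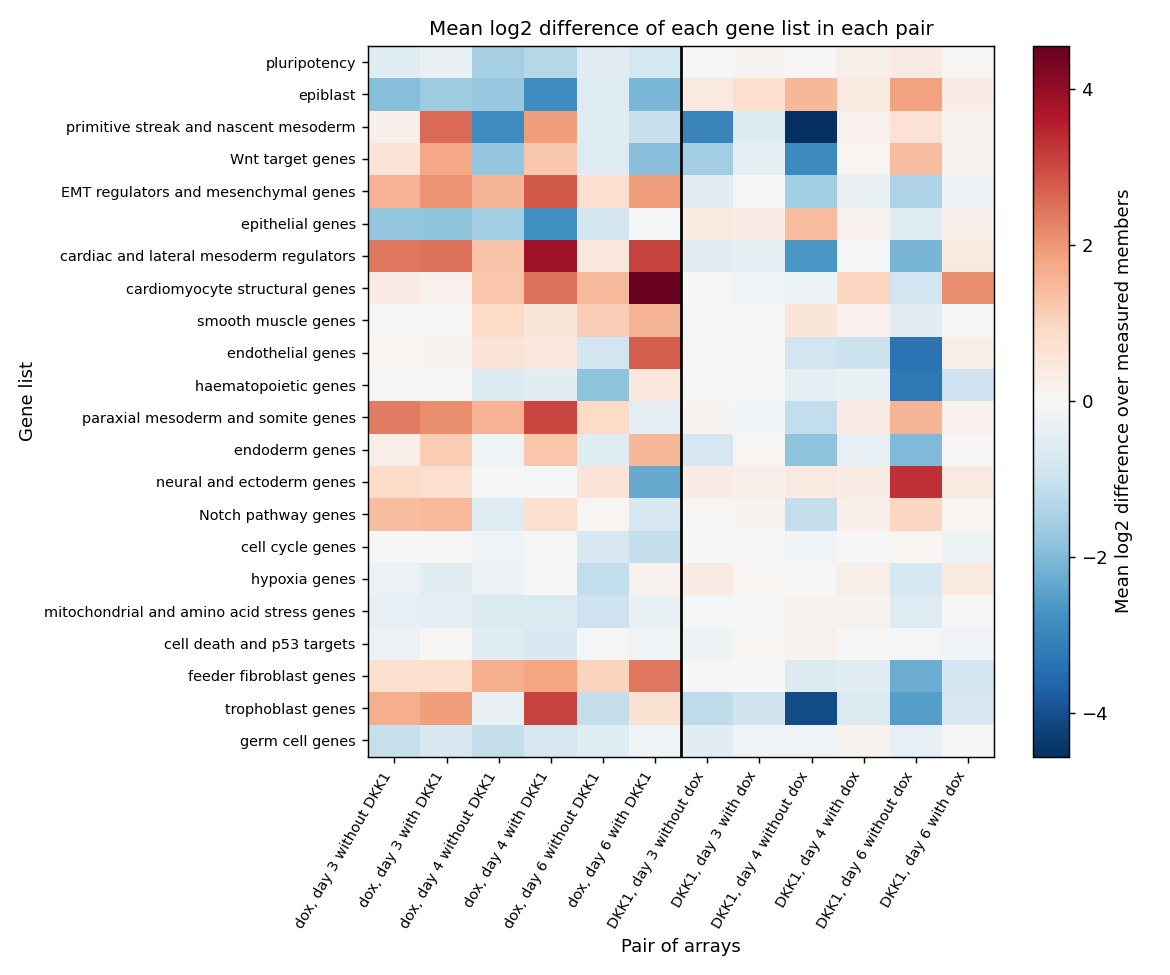
Mean log2 difference (colour scale) of the measured members of each of the 22 gene lists (vertical axis) in each of the 12 pairs of arrays (horizontal axis), dox pairs left of the black line and DKK1 pairs right of it. The cardiomyocyte list reached 4.50 in the day 6 dox pair with DKK1, and the primitive streak list −4.56 in the day 4 DKK1 pair without dox.

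The dox effect differed between day 6, when dox had been withdrawn, and days 3 and 4. Relative to the earlier days, the dox effect at day 6 was higher for Shisa3 (6.98 ± 0.786), Fgf5 (6.41 ± 0.552), a growth factor of the epiblast, Ptger4 (6.02), Igfbp3 (5.91) and Lbh (5.13). On day 6 without dox Shisa3 had 9.86 and 7.05, Fgf5 1 and 17.8 and Ptger4 8.23 and 18.7, each below the pseudocount in 1 of 2 arrays, so the size of these differences depended on it (Shisa3 7.33 and 6.28 with the 10th and 40th percentile). It was lower for Crabp1 (−7.90 ± 1.15), which binds retinoic acid, Tmem132c (−6.24), Pcdh19 (−5.81), Greb1l (−5.64) and Irx1 (−5.06). Crabp1 intensity without DKK1 went from 38.0 in untreated cells to 2836 with dox on day 3, and stood at 135.3 and 53.5 on day 6. The cell cycle list averaged from −0.18 to −0.01 in the 4 dox pairs of days 3 and 4, and −0.74 without and −1.07 with DKK1 on day 6. Their difference between the days was −0.83, and 12 of 27 fell relative to the earlier days (25 adjusted over the list alone), including Cdc6 (−1.67 ± 0.166), Mki67 (−1.49 ± 0.0991) and Aurkb (−1.39 ± 0.122).

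The camera test gave adjusted p = 5.19e-14 for the cell cycle list in this contrast (adjusted p = 0.763 with an estimated correlation). The epithelial list averaged between −2.81 and −1.59 in the 4 dox pairs of days 3 and 4, and −0.85 without and −0.05 with DKK1 on day 6. Of 26 epithelial genes 4 had a higher dox effect at day 6 (8 adjusted over the list alone), namely Esrp1 (3.24 ± 0.536), Ap1m2 (3.06 ± 0.354), St14 (2.10) and Spint2 (0.96), and the camera adjusted p was 2.76e-06 (adjusted p = 0.763 with an estimated correlation). In all, 710 genes were called for this difference, 318 higher and 392 lower. The count was 394 without the day 4 untreated array, and a fit on the pair differences called 652 genes. Without a single pair that fit called 17 (day 3 without DKK1), 15 (day 3 with DKK1), 943 (day 4 without DKK1), 6 (day 4 with DKK1), 815 (day 6 without DKK1) and 106 (day 6 with DKK1).

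At day 6, 448 genes were at least 2-fold higher with dox in both pairs and 282 at least 2-fold lower. Mean differences were highest in Shisa3 (6.85), Tbx18 (6.62), Tnnt2 (6.25), Myl4 (6.03) and Myl7 (6.01), but the pseudocount set part of their size and so of their order, with Tbx18 at 3.38 and 1.31 without dox, and Tnnt2 at 7.71 and Myl7 at 6.94 with DKK1 alone. The lowest were in the carbonic anhydrase genes Car4 (−4.52) and Car2 (−4.39), Gldc (−3.97), Cbln1 (−3.85) and Fgf15 (−3.32). These values had no test.

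**Figure D3:**
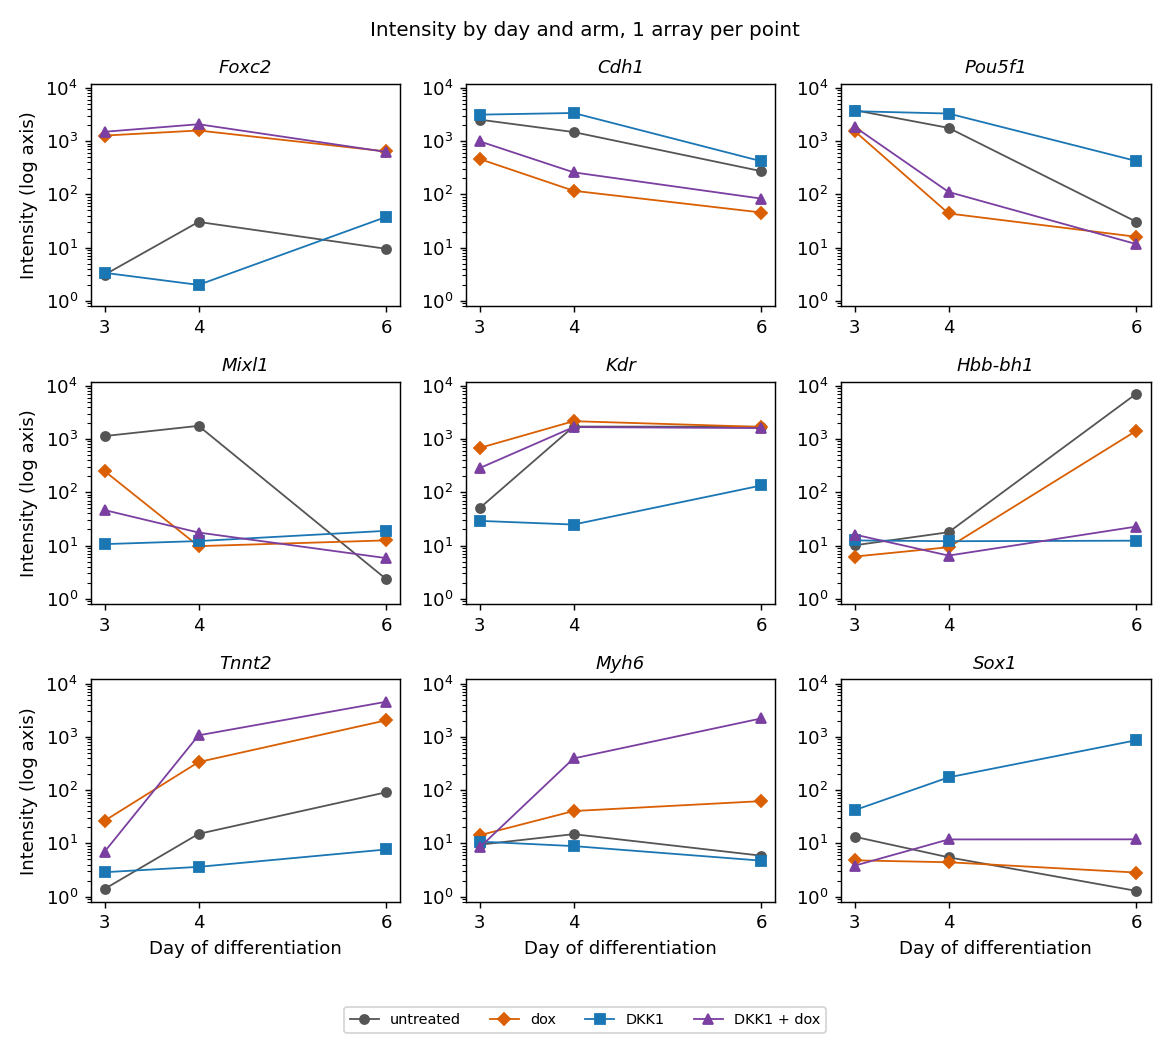
Intensity of 9 genes (log axes) against day of differentiation, 1 array per point, with a line for each of the 4 arms. Foxc2 was 3.10 in untreated cells and 1270 with dox on day 3, Hbb-bh1 reached 7109 in untreated cells on day 6, and Myh6 reached 2227 with DKK1 and dox on day 6.

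The arms with and without DKK1 ask whether Mesp1 acts in cells given DKK1, which ended on day 4. On days 3 and 4 the Wnt target list with DKK1 and dox lay 1.75 and 1.22 above DKK1 alone. It differed from dox alone by −0.40 and 0.10. Wnt target RNA in these cells was thus nearer to dox alone, so the arms do not show that Wnt signalling was inhibited there. With DKK1, dox raised Pdgfra by 6.25 ± 0.773, Foxc2 by 6.13 ± 0.71, Myocd by 5.97 ± 0.725, Nrp1 by 5.25 and Hand2 by 5.07 (n = 3 days). The lowest values with DKK1 were in Eras (−4.32), Pou3f1 (−4.32 ± 0.785), Pim2 (−4.14), Trh (−4.06) and L1td1 (−3.68). Without DKK1, dox raised Foxc2 by 5.77 ± 0.71, Myocd by 4.06 ± 0.725, Ptn by 3.8 and the Wnt inhibitor genes Shisa2 by 2.85 ± 0.394 and Sfrp1 by 2.59 ± 0.451. It lowered Gldc (−3.12), Cdh1 (−2.79 ± 0.374), Slain1 (−2.35), Tmprss2 (−2.33) and Grb7 (−2.24). Of the cardiac and lateral mesoderm regulators 14 rose with DKK1 (21 adjusted over the list alone) and 2 without it (4 adjusted over the list alone), and 0 fell in either. Their means were 3.14 with DKK1 (camera adjusted p = 3.47e-12, adjusted p = 0.149 with an estimated correlation) and 1.40 without (camera adjusted p = 4.73e-05, adjusted p = 0.293 with an estimated correlation).

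With DKK1 1083 genes were called, 638 higher and 445 lower, and without DKK1 139, 83 higher and 56 lower (after median centring 62 higher and 72 lower). Of the genes called without DKK1, 63 of the 83 higher and 47 of the 56 lower were also called with it, against 4.74 and 2.23 for independent draws, in arms that share the estimate of spread. The effects correlated across genes (r = 0.771 over 11163 genes, which are not independent replicates). The dox arrays with and without DKK1 correlated across genes at r = 0.986, 0.984 and 0.981 on days 3, 4 and 6. Without dox these values were 0.974, 0.895 and 0.862. On days 4 and 6 the arms with and without DKK1 thus differed mostly in the cells without dox, from which the dox effects are measured. Leaving out day 3, 4 or 6 gave 154, 0 and 1120 calls with DKK1, and 2, 0 and 254 without DKK1. Without the day 4 untreated array there were 28 calls in the arms without DKK1 and 816 in those with it.

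The test of the difference between these dox effects called 0 genes with limma (lowest adjusted p = 0.109), with 381 genes at an unadjusted p under 0.05 against 558.2 by chance. In simulated data the same test recovered 59.1% of genes with a 4-fold difference and 22.4% of those with a 2-fold difference.

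With DKK1 alone, which asks which genes depend on Wnt signalling, genes of mesoderm formation were lower in single pairs on days 3 and 4. Mixl1, a factor of the primitive streak, had an intensity of 1135 in untreated cells and 10.6 with DKK1 on day 3, and 1767 and 12.1 on day 4. Eomes, a factor of streak and endoderm, stood at 2008 without and 74.8 with DKK1 on day 4, and Evx1 at 1265 and 11.9. The primitive streak list averaged −3.00 on day 3, with 17 of 20 genes more than 2-fold lower, −4.56 on day 4 with 18 lower, and 0.65 on day 6. The Wnt target list averaged −1.56 on day 3 and −2.91 on day 4, with 11 of 15 genes more than 2-fold lower on day 4. DKK1 ended on day 4, and on day 6 the Wnt target list averaged 1.41, with 8 of 15 genes more than 2-fold higher. The day 6 differences were thus not measured under lower Wnt target RNA. On day 6 the neural and ectoderm list averaged 3.34, with 18 of 21 genes more than 2-fold higher, and the neural factors Sox1 and Zic1 had intensities of 866.5 and 2205 with DKK1 against 1.28 and 6.76 in untreated cells. The endothelial list averaged −3.37 on day 6 with 24 of 26 genes more than 2-fold lower, and the haematopoietic list −3.27. The endothelial receptor gene Kdr had 1697 without and 134.2 with DKK1, and the embryonic globin gene Hbb-bh1 7109 and 12.3. Over the 227 genes more than 2-fold apart the same way on days 3 and 4, the day 6 difference in that direction averaged 0.37 (SD 1.95 over genes).

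Over the 3 days without dox, 2 genes were called for DKK1, Sh3pxd2a (−2.22 ± 0.142, adjusted p = 0.00195) and St3gal6 (−2.05 ± 0.214, adjusted p = 0.0488), and 1445 had an unadjusted p under 0.05. Without day 3 the count was 24, and without day 4 or day 6 it was 0, and without the day 4 untreated array 1. List means were −2.30 for primitive streak genes (camera adjusted p = 6.73e-07, adjusted p = 0.424 with an estimated correlation), with 2 lower adjusted over the list alone. They were −1.75 for cardiac regulators (6.92e-09 by camera, adjusted p = 0.128 with an estimated correlation; 11 lower adjusted over the list alone) and −1.17 for EMT genes (1.08e-07 by camera, adjusted p = 0.109 with an estimated correlation; 7 lower adjusted over the list alone). They were 1.36 for neural genes (1.79e-07 by camera, adjusted p = 0.363 with an estimated correlation; 7 higher adjusted over the list alone) and 1.26 for epiblast genes (0.000346 by camera, adjusted p = 0.109 with an estimated correlation). The mean was −1.44 for endothelial genes (1.75e-07 by camera, adjusted p = 0.424 with an estimated correlation), −1.25 for haematopoietic genes (0.0196 by camera, adjusted p = 0.547 with an estimated correlation) and −1.54 for endoderm genes (5.3e-05 by camera, adjusted p = 0.109 with an estimated correlation; 6 lower adjusted over the list alone). It was −2.59 for trophoblast genes (2.77e-05 by camera, adjusted p = 0.128 with an estimated correlation; 5 lower adjusted over the list alone), −0.96 for feeder fibroblast genes (0.00395 by camera, adjusted p = 0.424 with an estimated correlation; 3 lower adjusted over the list alone) and 0.41 for epithelial genes (0.0117 by camera, adjusted p = 0.842 with an estimated correlation). On days 3, 4 and 6 the neural mean was 0.33, 0.40 and 3.34, the endothelial −0.07, −0.88 and −3.37, the haematopoietic −0.04, −0.45 and −3.27, the feeder fibroblast −0.01, −0.62 and −2.26 and the epithelial 0.40, 1.40 and −0.57. The first 4 of these were thus furthest from 0 on day 6, and the epithelial list went both ways. Over all genes 0 members of these lists were called.

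With dox present the DKK1 difference covered fewer genes in each pair. On days 3, 4 and 6, 295, 1196 and 1555 genes were over 2-fold apart with and without DKK1 in cells without dox, and 151, 169 and 177 in cells with dox. The primitive streak list in the DKK1 pairs with dox averaged −0.62, 0.19 and 0.17, and the Wnt target list −0.40, 0.10 and 0.11. The endothelial list in these pairs averaged −0.01, −0.98 and 0.26, and on day 4, with 10 of 26 genes more than 2-fold lower, it was no closer to 0 than without dox (−0.88). Cardiomyocyte structural genes differed on day 6, with a mean of 2.13 and 14 of 19 genes more than 2-fold higher with DKK1 and dox than with dox alone. Among them the atrial light chain gene Myl7 had 332.7 and 4714, and the myosin gene Myh6 62.2 and 2227. The counts per pair had no test, and the interaction test above called 0 genes.

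Over all 6 pairs DKK1 had 0 called genes with limma (lowest adjusted p = 0.334), with 1399 at an unadjusted p under 0.05 against 558.2 by chance. Members of its lists with this adjusted p included Cdx2 (−2.61, adjusted p = 0.334), Col1a1 (−2.36, adjusted p = 0.334) and Sox2 (2.07, adjusted p = 0.334). List means were 0.84 for neural and ectoderm genes (higher in 6 of 6 pairs; 3 higher adjusted over the list alone; camera adjusted p = 4.56e-06, adjusted p = 0.665 with an estimated correlation) and 0.88 for epiblast genes (higher in 6 of 6 pairs; 6 higher adjusted over the list alone; camera adjusted p = 4.7e-05, adjusted p = 0.665 with an estimated correlation). The mean was −0.69 for EMT genes (lower in 6 of 6 pairs; 1 lower adjusted over the list alone; camera adjusted p = 4.56e-06), −1.68 for trophoblast genes (6 of 6; 2 lower adjusted over the list alone; 0.000175 by camera), −0.71 for feeder fibroblast genes (6 of 6; 0.0006 by camera) and −0.84 for haematopoietic genes (6 of 6; 0.0404 by camera). It was −0.89 for cardiac regulators and −0.84 for endothelial genes (each lower in 5 of 6 pairs; 4.7e-05 by camera), −0.81 for endoderm genes (4 of 6; 0.00919 by camera) and 0.33 for epithelial genes (higher in 5 of 6; 9.59e-05 by camera). These 8 lists had an adjusted p = 0.665 with an estimated correlation. Primitive streak genes averaged −1.20 (lower in 3 of 6; 0.000651 by camera, adjusted p = 0.67 with an estimated correlation) and hypoxia genes 0.07 (higher in 5 of 6; 0.0271 by camera, adjusted p = 0.686 with an estimated correlation), the latter −0.00239 without the day 6 pair with dox (hypoxia genes list, DKK1 effect over 6 pairs). Single pairs carried much of other means. Without the day 6 pair without dox the mean was 0.35 for neural, −0.34 for endothelial, −0.36 for haematopoietic, −0.40 for feeder fibroblast, −0.57 for endoderm and 0.51 for epithelial genes. Without the day 4 pair without dox it was −0.52 for primitive streak genes, −0.53 for cardiac regulators and 0.12 for epithelial genes.

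**Figure D4:**
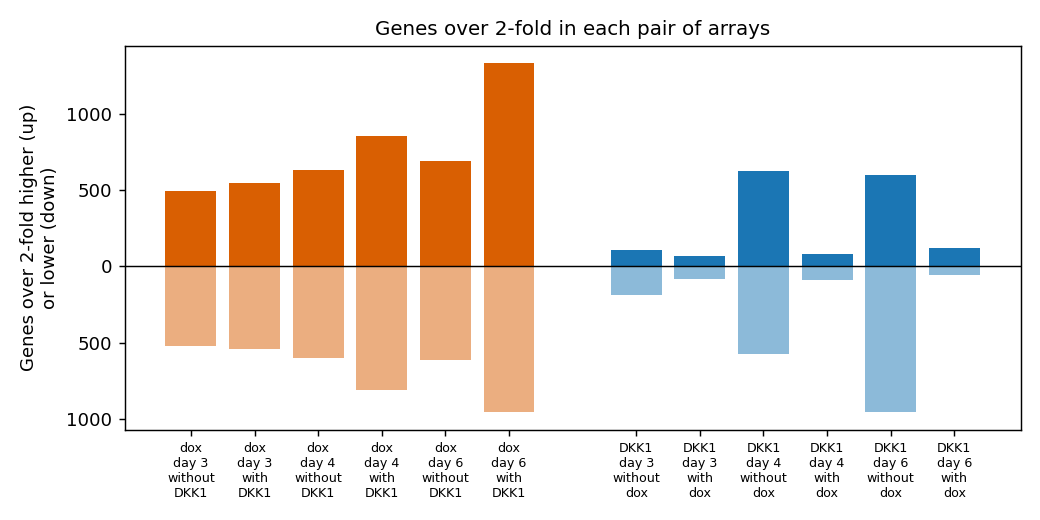
Number of genes over 2-fold higher (upward bars) or lower (downward bars) in each pair of arrays for dox (orange) and DKK1 (blue). DKK1 bars with dox total 151, 169 and 177 genes on days 3, 4 and 6.

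Time in culture had the largest count of calls. From day 3 to day 6 the first genes named here were chosen among called genes with the same direction in all 4 arms. The mesenchymal genes Col3a1 (5.98 ± 1.11) and Postn (5.85 ± 0.954) rose, as did the immediate early gene Fos (5.77 ± 0.364), Igfbp5 (5.71) and the endothelin receptor gene Ednrb (5.17). Tdgf1 (−6.28 ± 1.16), a Nodal co-receptor, Pou5f1 (−5.55 ± 0.833), Eomes (−5.41 ± 1.06), Dppa5a (−5.10 ± 0.36) and L1td1 (−5.0) fell. Of 18 pluripotency genes 12 fell and 2, Klf2 (3.39) and Klf4 (2.88), rose (13 and 2 adjusted over the list alone), with a mean of −1.88 (SD 0.222 over 4 arms; camera adjusted p = 0.00023, adjusted p = 0.197 with an estimated correlation). Endothelial genes rose in 17 of 26 cases and fell in 0 (19 and 1 adjusted over the list alone), including Cdh5 (4.68 ± 1.1) and Tek (3.68 ± 0.91), with a mean of 1.99 (SD 1.43; camera adjusted p = 0.000227, adjusted p = 0.552 with an estimated correlation). With DKK1 alone the endothelial list differed from untreated cells by −0.07 on day 3 and −3.37 on day 6. Dox added to DKK1 changed it by 0.15 and 2.75 on these days. The endothelial rise was thus smaller with DKK1 alone than in untreated cells or with DKK1 and dox. Of 16 feeder fibroblast genes 12 rose and 1, Thy1 (−2.47), fell (13 and 1 adjusted over the list alone), with a mean of 2.48 (SD 1.13; camera adjusted p = 0.000358, adjusted p = 0.338 with an estimated correlation). Cell cycle genes fell in 13 of 27 cases (13 adjusted over the list alone), with a mean of −0.54 (SD 0.521; camera adjusted p = 1.1e-05, adjusted p = 0.552 with an estimated correlation). The dox difference of the cell cycle list was −0.01 on day 3 and −0.74 on day 6 without DKK1, and −0.02 and −1.07 with DKK1. The fall was thus larger in the arms with dox than in those without.

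In this comparison 4060 genes were called, 2338 higher and 1722 lower (after quantile normalization 1866 higher and 2136 lower). The counts without an arm were 2303 (untreated), 1112 (dox), 5011 (DKK1) and 864 (DKK1 with dox). From day 3 to day 4 there were 325 calls, 282 higher and 43 lower (125 and 58 after quantile normalization, 126 and 41 after median centring), and from day 4 to day 6 308, 141 higher and 167 lower (200 and 146 after median centring). Leaving out the untreated, dox, DKK1 or DKK1 with dox arm gave 7, 3, 874 and 3 calls from day 3 to day 4, and 30, 0, 1615 and 0 from day 4 to day 6. Without the day 4 untreated array the counts were 15 and 54.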

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

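The tests of array scaling, stress, doxycycline without the transgene, swapped or exchanged arrays and the share of mesoderm cells were chosen after the results were seen, and the counts over other splits of the arrays were planned. No condition had 4 or more arrays, so no array was tested as an outlier.

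The dox effect at day 6 differed from that at days 3 and 4 in 710 genes by a test of the difference. Gene lists whose dox effect differed in this way by camera with the preset correlation were Wnt targets (−1.69), epithelial genes (1.56), cardiomyocyte structural genes (1.90), smooth muscle genes (0.98), paraxial mesoderm genes (−2.05) and cell cycle genes (−0.83). Lists whose dox effect differed with DKK1 were epiblast (−0.75), primitive streak (2.21), EMT (0.94), cardiac regulators (1.74), cardiomyocyte (1.35), endothelial (1.20), endoderm (1.46), neural (−1.02), hypoxia (0.40) and trophoblast genes (1.81). Without day 6 the endothelial genes list, DKK1 by dox interaction, was at −0.0203 and the hypoxia genes list, DKK1 by dox interaction, at −0.0322. Single days carried other lists too. In the dox pairs without and with DKK1 the neural list averaged 0.60 and −2.31 on day 6. It averaged 0.89 and 0.78 on day 3, and −0.04 and −0.09 on day 4. The cardiomyocyte list averaged 1.48 and 4.50 on day 6, against 0.39 and 0.20 on day 3. The primitive streak list averaged −2.83 and 1.91 on day 4, and −0.55 and −1.03 on day 6. None of these 16 list calls held with an estimated correlation, and the difference with DKK1 called 0 single genes with limma (381 at an unadjusted p under 0.05). Among 1919 tested probe sets without a single gene name, which the comparisons left out, 234 were called for dox, 125 higher and 109 lower.

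Other splits of the arrays within their blocks bear on whether chance could give as many calls. For the dox effect over 6 pairs 1 of 32 splits, the real one, gave as many as 1773 genes and the highest other gave 10. Random labels within independent pairs would thus seldom give as many. This is the lowest share that 32 splits can give. The pairs are different conditions, perhaps from a single series of cultures, so a chance difference between cultures is not excluded. For DKK1 over 6 pairs the real count was 0 (highest other 0), so all 32 splits had to give as many and the count says nothing about chance, and the same holds for the 4 of 4 splits of the difference of the dox effects with DKK1 (real 0, highest other 0). The splits were too few for a share under 0.05 in the other comparisons. Of 4 splits, 1 gave as many genes for dox without DKK1 (139, highest other 0), for dox with DKK1 (1083, highest other 0) and for DKK1 without dox (2, highest other 0). Of 8 splits, 1 gave as many for day 4 minus day 3 (325, highest other 0), day 6 minus day 4 (308, highest other 7) and day 6 minus day 3 (4060, highest other 0). For the dox effect at day 6 minus days 3 and 4, fitted on pair differences, 1 of 15 splits gave as many (652, highest other 1).

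The broad dox effect was weighed against array scaling and doxycycline itself. After quantile normalization 1635 of the 1773 calls were shared with the deposited scale, which argues against array scaling as the cause. Mitochondrial stress from doxycycline predicts a rise of the mitochondrial and amino acid stress list, whose mean was −0.56 (SD 0.238 over 6 pairs), so no net rise was seen. All cells given dox carried the transgene, and Mesp1 induction could lower the same genes and mask a rise. The value therefore cannot exclude stress from the drug. Doxycycline acting without the transgene stays open, since 0 arrays of dox-treated cells without the inducible gene are in the series. Induction of Mesp1 remains a candidate explanation that these arrays could not separate from the drug.

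Endothelial and haematopoietic genes were lower with dox on day 6 without DKK1, and endothelial genes were higher with dox on day 6 with DKK1. The endothelial list averaged −0.89 with 13 of 26 genes more than 2-fold lower without DKK1, and 2.75 with 24 higher with DKK1, while the haematopoietic list averaged −1.85 with 9 of 13 lower, and 0.47 with a median of 0.13 and 3 higher (2 single pairs, not tested as a difference on day 6). The DKK1 difference on day 6 was −3.37 without and 0.26 with dox for the endothelial list. For the haematopoietic list it was −3.27 and −0.95. The contrast thus lay mostly in the arrays without dox. The haematopoietic value stayed at −1.85 or lower after quantile normalization and median centring, and Mesp1 was at least 2.86 higher in the dox array of both day 6 pairs, which argues against scaling and against a swap of arrays with and without dox. An exchange of the untreated and DKK1 arrays of day 6 stays open: the 227 genes more than 2-fold apart the same way on days 3 and 4 averaged 0.37 in that direction on day 6, with an SD of 1.95 over genes. A lower share of all mesoderm cells would lower cardiac, cardiomyocyte and smooth muscle lists too. Their mean was 1.03 (SD 0.495 over the 3 lists) in the pair without DKK1, so no net fall was seen. Of 29 cardiac regulators 10 were more than 2-fold higher in this pair and 7 lower. The 3 lists were also higher on average with dox over the 6 pairs, so a rise within fewer mesoderm cells could mask a fall. The value therefore cannot exclude a lower share. A biological effect of DKK1 on the response to dox stays open.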

How the results depend on the processing

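Settings named as added (leaving out the day 4 untreated array, and the fit on pair differences) were chosen after the data were seen. Arrays were paired by day and the other treatment, since with 1 array per condition there were no replicate numbers to pair by. Settings other than leaving out arrays kept 74 of 90 counts of calls, 78 of 84 single pair counts, 883 of 900 named gene results and 854 of 882 list results. A kept count lay within a fixed fold of the main count or stayed at 0. The kept counts of calls thus include every setting of DKK1 over 6 pairs and of the interaction, which stayed at 0. For the moved counts the cause was not tested, except that no filter tests more genes and leaving out arrays leaves fewer. Dim signal over background limits genes near the filter.

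The dox effect over 6 pairs called 2750 genes with an additive model and 3219 with 2-way interactions. Dox without DKK1 called 86 with no filter and 71 without trend and robust options, and dox with DKK1 1653 with 2-way interactions. DKK1 without dox called 1 with the 40th percentile pseudocount, 6 with no filter, 1 with the stricter filter, 1 with the mean of probe sets and 0 with 2-way interactions. Day 4 minus day 3 called 183 after quantile normalization, 167 after median centring and 182 with no filter, and day 6 minus day 4 198 with no filter. The dox effect at day 6 minus days 3 and 4 called 289 without trend and robust options and 167 with 2-way interactions. With no filter the number of genes over 2-fold, DKK1 day 3 without dox, was 516, of genes over 2-fold, DKK1 day 3 with dox, 419, of genes over 2-fold, DKK1 day 4 with dox, 336 (103 with the 40th percentile pseudocount) and of genes over 2-fold, DKK1 day 6 with dox, 298 (114 with the stricter filter). DKK1 over 6 pairs and the interaction called 0 under every setting run.

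Leaving out each pair, day or arm in turn gave 279 to 1363 calls for dox over 6 pairs, 0 to 254 for dox without DKK1, 0 to 1120 for dox with DKK1 and 0 to 24 for DKK1 without dox. It gave 3 to 874 for day 4 minus day 3, 0 to 1615 for day 6 minus day 4, 864 to 5011 for day 6 minus day 3 and 6 to 943 for the dox effect at day 6 minus days 3 and 4. Without the day 4 untreated array the counts were 28, 816, 1, 15, 54, 3679 and 394 for dox without and with DKK1, DKK1 without dox, the 3 day contrasts and the day 6 difference. Of named gene results 326 of 648 kept their call when arrays were left out, and 34 of 34 were lost for dox with DKK1 without day 4. The mean of the hypoxia genes list, DKK1 effect over 6 pairs, ranged from −0.00239 (without day 6 with dox) to 0.25. That of the endothelial genes list, DKK1 by dox interaction, ranged from −0.0203 (without day 6) to 1.85, and that of the hypoxia genes list, DKK1 by dox interaction, from −0.0322 (without day 6) to 0.73.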

Other observations

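Except for the heat shock genes, the lists and tests below were chosen after the data were seen. Of 15 measured Hox genes, which pattern the body axis, 4 rose with dox, Hoxb2 by 3.75, Hoxb3 by 3.31, Hoxa2 by 2.18 and Hoxb4 by 1.51, and 0 fell. Among those that did not pass were Hoxb1 (2.17, adjusted p = 0.218), Hoxd1 (0.34, adjusted p = 0.741) and Hoxa3 (0.07, adjusted p = 0.747). The list mean was 1.07 (SD 0.845; higher in 5 of 6 pairs, exact sign-flip p = 0.0625; camera p = 0.0184, p = 0.218 with an estimated correlation), and it was −0.34 in the day 6 pair without DKK1. In the DKK1 pairs the list averaged −0.70 (lower in 6 of 6, exact sign-flip p = 0.0313; camera p = 0.021, p = 0.119 with an estimated correlation). Of 10 retinoic acid genes Aldh1a2 and Rarb (3.15) rose with dox (mean 0.95, SD 0.772, exact sign-flip p = 0.0625; camera p = 0.312, p = 0.339 with an estimated correlation). The retinoic acid list averaged 1.08 to 1.96 in the 4 dox pairs of days 3 and 4, and 0.23 without and −0.14 with DKK1 on day 6.

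The list of Wnt inhibitor genes had a mean of 1.13 with dox (SD 0.412; above 0 in 6 of 6 pairs, exact sign-flip p = 0.0313; camera p = 0.0527, p = 0.0991 with an estimated correlation). Of 10 measured genes Shisa2 and Sfrp1 rose, while Dkk1 itself (2.23, adjusted p = 0.117), Sfrp2 (−0.65), Frzb (−0.23) and Sfrp4 (−0.15) did not pass, and in the arms with DKK1 Sfrp2 fell (−1.38, adjusted p = 0.0276). In the DKK1 pairs the list averaged 0.09 (SD 0.305).

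Immediate early genes, which respond within minutes to growth factors and stress, rose from day 3 to day 6 in 12 of 18 measured cases and fell in 1 (Fosl2, −0.69), with a mean of 2.08 (SD 0.7; 4 of 4 arms, exact sign-flip p = 0.125; camera p = 4.34e-05, 0.192 with an estimated correlation). The mean was 1.73 in untreated cells, 2.67 with dox, 1.26 with DKK1 and 2.65 with both. Handling stress of the day 6 cultures may have raised them: the heat shock list averaged 0.31 (SD 0.349), within its spread, with −0.04 in untreated cells, 0.63 with dox, 0.06 with DKK1 and 0.59 with both, so this stays open. The cell types of the day 6 cultures are a second candidate explanation, and the lowest arm with dox exceeded the highest arm without by 0.92, under the 1 set for it, so this stays open too. For dox over 6 pairs the heat shock list averaged −0.03 (SD 0.322), with Bag3 (0.90), Dnajb4 (0.76) and Dnajb1 (0.35) of 11 genes higher and Hspa4l (−1.13) lower, and the immediate early list 0.05 (SD 0.858). Both means changed sign by day: in the 4 dox pairs of days 3 and 4 heat shock lay between −0.29 and −0.19 and immediate early genes between −0.83 and −0.05, and on day 6 without and with DKK1 they were 0.42 and 0.34, and 0.78 and 1.34.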
